A study of Mus musculus with 6 samples.

How the data were processed

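Single-cell RNA sequencing was carried out on dissociated mouse knee joints at 5 ages with a droplet method (10x Genomics), in which each cell receives a barcode and each captured transcript a unique molecular identifier (UMI). The series holds 6 samples. The deposited table has cells from 5 of them, the whole knee joints at E12.5, E13.5, E15.5, E18.5 and P5. The P5 meniscus sample was not analysed here, so the planned comparison of P5 knee with P5 meniscus was not made. Per the labels, the 4 embryonic libraries came from mice with the Lgr5-GFP reporter allele, and the P5 library from C57BL/6 mice with no reporter named.

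The authors deposited, for each cell, 4 values: the total UMI count, the number of genes detected, the EGFP UMI count and the CreERT2 UMI count, per the file headers. All are whole numbers, and the UMI counts were deposited without normalization. Cell Ranger 3.1.0, Seurat 3 and the mm10 build are named in the submitters' processing notes. How the EGFP and CreERT2 sequences were added to the reference, whether their UMIs are included in a cell's total, and which filters on cells and doublets were applied are not given in the sources used here. Because all libraries were counted by the authors before deposit, a difference in filter or reference between libraries would pass into every value below. Expression of other mouse genes was not analysed here, so cells have no type, and the gene lists fixed for this tissue and the tests that needed them were not used. EGFP, the gene named by the rule fixed before the data were examined, had values at E12.5 only and was marked as missing in the other libraries. The comparison across ages was therefore made on CreERT2, which is transcribed from the same allele. That choice, and all measures and alternatives for CreERT2, were made after seeing the data.

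Samples were assigned to ages by their labels, and rows of the table to samples by the sample names in the labels. The number of columns of values that were left unused was 0. There was 1 library per age, so no test between ages was possible and no p-value is given. Cells are not replicates. Each library also differed from the others in its month of sequencing, so age cannot be separated from batch.

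A cell was called positive with at least 1 UMI. Shares of cells have exact Clopper-Pearson 95% intervals. Sums of UMIs have exact Poisson 95% intervals and were divided by the total UMIs of the library and given per 1000000 UMIs (CPM). Ratios of levels have exact conditional 95% intervals. Where 0 UMIs were counted, the limit was set at 3 counts per library. All intervals and limits cover counting error only, not the spread between animals or preparations. No cell was removed and no doublet caller was run, since it would need other genes.

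Because the chance of seeing a UMI grows with the depth of a cell, each cell was also thinned to 1500 UMIs, and separately to 4000 UMIs, leaving out shallower cells. The thinned share is the exact hypergeometric expectation, and its interval is that of the nearest whole number of cells. The number of cells expected to carry at least 2 CreERT2 UMIs was computed by placing the library's CreERT2 UMIs on cells in proportion to their UMI totals. Cells were ranked by UMI total and divided into 4 equal groups, from the shallowest to the deepest. The number of genes in each positive cell was compared with the median of the 50 negative cells of the same library nearest in UMI total. Both the thinning and the expectation were tested on simulated counts placed on the real cells of each library. Over 100 simulations with an even spread, the mean ratio of counted to expected cells was 1.02 on 11135 cells at E12.5, 1.08 on 9400 cells at E13.5 and 0.965 on 5833 cells at E15.5. With the UMIs confined to 1.0% of cells the mean ratio was 3.56, 11.6 and 7.66. More cells than that were positive in each of these libraries (5.37%, 2.62% and 3.14%). The setting therefore checks the measure only, and its ratios give no share of cells for the real data. At E18.5, with 23 UMIs on 4431 cells, the mean ratio was 1.27 with an even spread, and some simulations with confined UMIs gave a ratio of 0. The alternatives were higher minimum counts, leaving out shallow or deep cells, leaving out the 1% of cells with the highest counts, per-cell scaling and a log scale. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. The position of Lgr5 was taken from GENCODE M21 on GRCm38, the assembly called mm10.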

Results

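Whole knee joints of mouse embryos and pups were profiled by single-cell RNA sequencing at E12.5, E13.5, E15.5, E18.5 and P5, with 1 library per age. The 4 embryonic libraries carried a reporter allele of Lgr5 from which EGFP and CreERT2, a tamoxifen-inducible Cre recombinase, are transcribed together. Lgr5 encodes a receptor for R-spondins that strengthens Wnt signalling. It lies on the minus strand of chromosome 10 from 115450311 to 115587780 (mm10, ENSMUSG00000020140.15). The P5 library was C57BL/6 with no reporter named, so no transgene count was expected there. The table held 37506 cells and 408859667 UMIs.

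The E12.5 library had 11135 cells and 155302893 UMIs, with a median of 11275 UMIs and 3252 genes per cell. The E13.5 library was the shallowest, with 9400 cells, 34190412 UMIs and medians of 3004 UMIs and 1468 genes. The E15.5 library had 5833 cells, 88525060 UMIs and medians of 14143 UMIs and 3157 genes. The E18.5 library had 4431 cells, 57209271 UMIs and medians of 12407 UMIs and 2691 genes. The P5 library had 6707 cells, 73632031 UMIs and medians of 10585 UMIs and 2574 genes. The lowest UMI total of any cell was 504 at E12.5, 1550 at E13.5, 4406 at E15.5, 2880 at E18.5 and 2635 at P5. The labels name 1 version of the droplet protocol for all samples. The E12.5 library nevertheless shared only 6 cell barcodes with the other 4 libraries, where 372 were expected from the 322 barcodes shared among those 4.

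The Lgr5 reporter transcript was first compared between ages. CreERT2 was detected at every embryonic age and not at P5. Its level was 4.11 counts of CreERT2 per 1000000 UMIs (CPM) at E12.5 (95% interval 3.795 to 4.440, 638 UMIs). It was 8.69 CPM at E13.5 (7.73 to 9.73, 297 UMIs), which was 2.11 times the E12.5 level (1.84 to 2.43). The level was 3.07 CPM at E15.5 (2.72 to 3.46, 272 UMIs), and E13.5 stood 2.83 times above it (2.39 to 3.35). At E18.5 the level was 0.402 CPM (0.255 to 0.603, 23 UMIs), and E15.5 stood 7.64 times above E18.5 (4.99 to 12.3). In the P5 library 0 CreERT2 UMIs were counted, which allows up to 0.0407 CPM. The differences between the embryonic ages above exceeded counting error, and with 1 library per age none has a replicate check. The E12.5 barcodes may come from another list, so library chemistry cannot be told apart from age in any CreERT2 comparison with E12.5. Counted per cell without scaling to depth, both comparisons with the shallow E13.5 library turned, to 0.551 times for E13.5 over E12.5 (0.479 to 0.634) and 1.48 times for E15.5 over E13.5 (1.25 to 1.75). The P5 library differed from the embryonic ones in genotype as well as age, so its count of 0 says nothing about age.

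**Figure D1:**
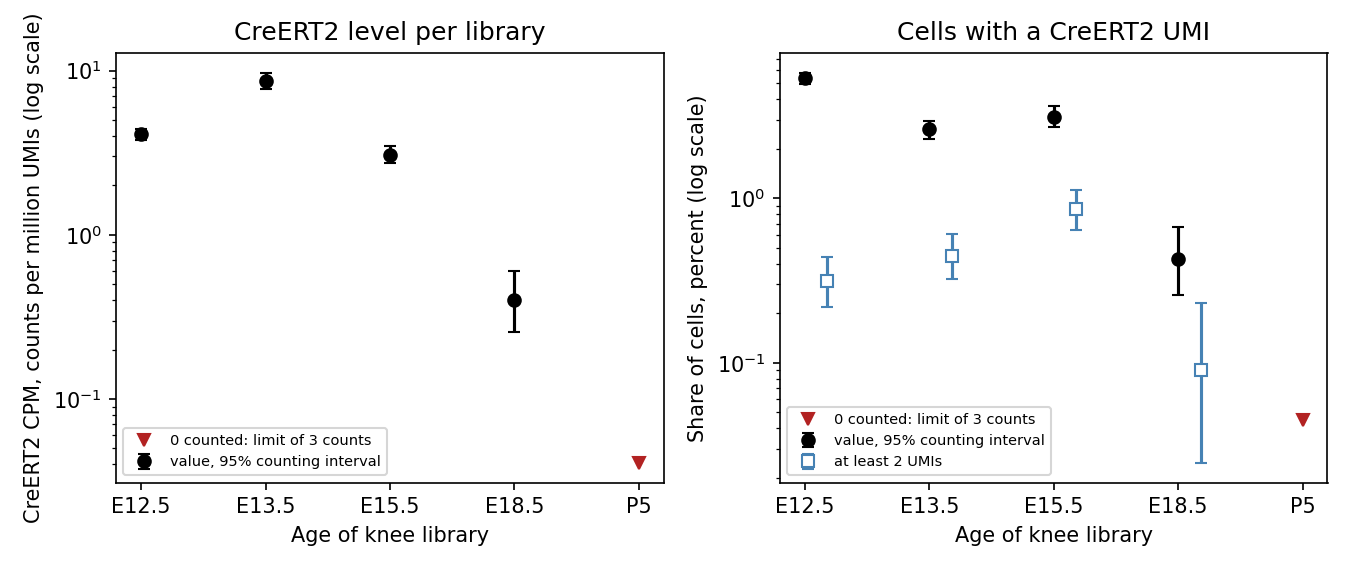
CreERT2 in knee libraries by age: CreERT2 CPM (left) and the share of cells with at least 1 or at least 2 CreERT2 UMIs (right), both on log axes, with bars for 95% counting intervals. The level was highest at E13.5 (8.69 CPM) and the share with at least 1 UMI highest at E12.5 (5.37%), while the P5 triangle marks the limit that a count of 0 allows.

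CreERT2 UMIs were found in few cells at any age. At E12.5, 598 of 11135 cells had at least 1 (5.37%, 4.96 to 5.81). The share was 2.62% at E13.5 (246 cells, 2.30 to 2.96), 3.14% at E15.5 (183 cells, 2.70 to 3.62) and 0.429% at E18.5 (19 cells, 0.258 to 0.669). At P5 it was 0 of 6707 cells, which allows a share of up to 0.0447%. These shares followed a different order from the levels in CPM, and the depth of the libraries differed. With every cell thinned to 1500 UMIs the share was 0.609% at E12.5 (0.473 to 0.777), 1.42% at E13.5 (1.20 to 1.69), 0.443% at E15.5 (0.291 to 0.652) and 0.0773% at E18.5 (0.0140 to 0.198). That depth left out 336 cells at E12.5 and 0 cells in the other libraries. With 4000 UMIs per cell the shares were 1.66% at E12.5 (1.42 to 1.93), 2.03% at E13.5 (1.53 to 2.67), 1.09% at E15.5 (0.846 to 1.40) and 0.200% at E18.5 (0.0935 to 0.388). At this depth 1013 cells at E12.5, 6807 at E13.5, 0 at E15.5 and 27 at E18.5 were too shallow to enter, and the E12.5 and E13.5 intervals overlapped.

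More cells had at least 2 CreERT2 UMIs at E13.5 and E15.5 than a spread over all cells by depth alone would give, which does not show that positive cells differ in level. At E15.5, 50 of the 183 positive cells had at least 2 CreERT2 UMIs (27.3%, 21.01 to 34.4), and 2 cells had 9. Those 50 cells held 51.1% of the library's 272 CreERT2 UMIs. At E13.5, 42 of 246 positive cells had at least 2 (17.1%, 12.6 to 22.4), and the highest count was 4. At E12.5 it was 35 of 598 (5.85%, 4.11 to 8.05), with a highest count of 3. At E18.5, 4 of 19 positive cells had 2 UMIs (21.1%, 6.05 to 45.6). Placing the same UMIs on cells by depth alone would give 26.6 such cells at E12.5, 6.00 at E13.5, 6.94 at E15.5 and 0.0630 at E18.5. The counted number was therefore 1.31 times the expected at E12.5 (0.915 to 1.83). That interval includes an even spread, but the ratio lay slightly above the 0.729 to 1.28 that held 95% of 100 simulated even spreads on the same cells. The counted number was 6.999 times the expected at E13.5 (5.04 to 9.46), 7.20 times at E15.5 (5.35 to 9.49) and 63.5 times at E18.5 (17.3 to 163), the last from 4 cells. For at least 3 UMIs the E12.5 library had 5 cells where 1.32 were expected, a ratio of 3.79 (1.23 to 8.85).

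**Figure D2:**
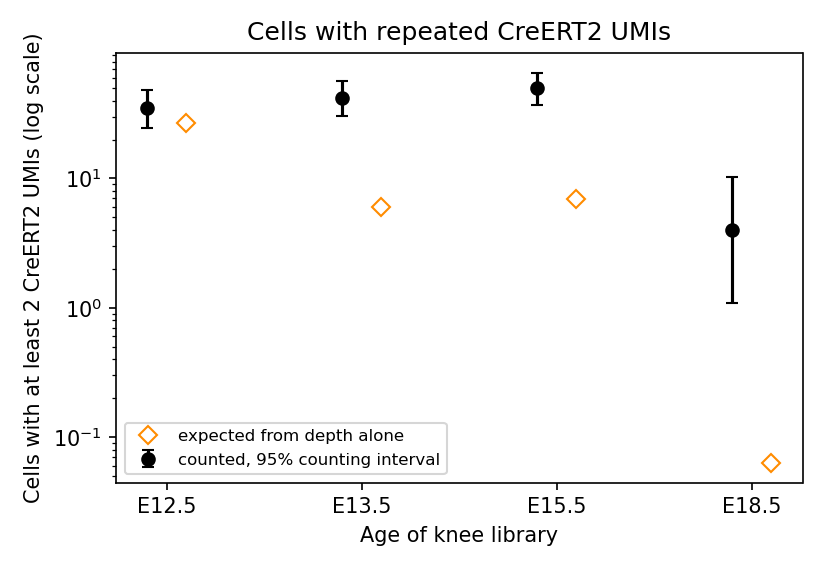
Cells with at least 2 CreERT2 UMIs in each embryonic knee library, on a log axis: cells counted, with 95% counting intervals, and cells expected if the UMIs fell on cells in proportion to depth. The counted number exceeds the expected at E13.5, E15.5 and E18.5, and the interval at E12.5 includes the 26.6 cells expected.

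At E13.5 and E15.5, and by a small margin at E12.5, positive cells more often than not had more genes detected than negative cells of the same depth. At E15.5 they had a median of 263 more genes than the 50 negative cells nearest in UMI total (quartiles 109 to 426), and 158 of 183 lay above their matched cells (86.3%, 80.5 to 91.0). Among the 50 cells with at least 2 UMIs it was 48 (96.0%, 86.3 to 99.5). At E13.5, 188 of 246 lay above (76.4%, 70.6 to 81.6), with a median of 61.8 more genes (quartiles 2.75 to 118). At E12.5 the share was 54.3% (325 of 598, 50.3 to 58.4) and the median 20.5 more genes (quartiles -96.8 to 166). At E18.5 it was 52.6% (10 of 19, 28.9 to 75.6). Negative cells themselves lay above their matched cells in 49.8% of cases at E12.5, 49.9% at E13.5, 50.02% at E15.5 and 50.2% at E18.5.

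The relation of CreERT2 to the depth of a cell also differed between ages. Across cells at E12.5 the level was even, at 4.15 CPM in the shallowest of 4 equal groups (3.16 to 5.36) and 4.004 in the deepest (3.57 to 4.48). At E13.5 it was 17.0 CPM in the shallowest group (13.53 to 21.2), 10.7 and 6.93 in the middle groups, and 6.17 in the deepest (4.97 to 7.56). At E15.5 it was 3.81 in the shallowest (2.85 to 5.00) and 2.82 in the deepest (2.28 to 3.45), a difference within counting error. At E18.5, 12 of the 23 UMIs came from the shallowest group and 0 from the deepest 1107 cells, where up to 3 counts cannot be excluded. Positive cells at E18.5 had a median of 10097 UMIs and negative cells 12419.

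**Figure D3:**
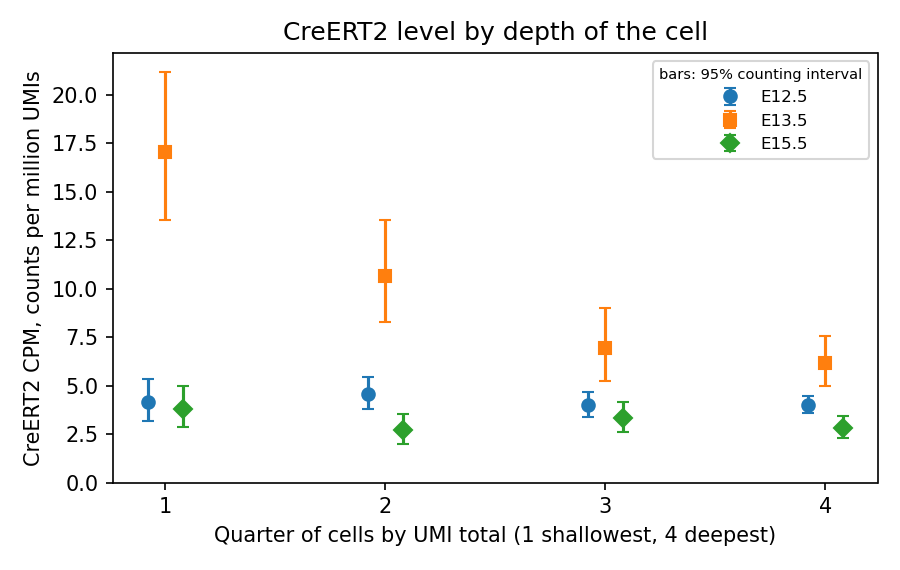
CreERT2 CPM in 4 equal groups of cells ranked by UMI total, at E12.5, E13.5 and E15.5, with bars for 95% counting intervals. The E13.5 level ran from 17.0 in the shallowest cells to 6.17 in the deepest, and the E12.5 level was 4.15 in the shallowest and 4.004 in the deepest.

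EGFP, which is transcribed together with CreERT2, was counted far less often in the 1 library with values. At E12.5, 18 of 11135 cells had 1 EGFP UMI each (0.162%, 0.0958 to 0.255), and no cell had more. The level was 0.116 CPM (0.0687 to 0.183), and CreERT2 UMIs were 35.4 times as frequent (22.2 to 60.2). How the EGFP and CreERT2 sequences were added to the reference is not given. This ratio therefore cannot be read as a difference in expression between them. The number of cells with both EGFP and CreERT2 was 0, where 1.54 were expected from depth and the 2 totals alone, so a joint presence was not detectable at this depth.

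Finally, the number of genes detected at a given depth was compared across ages. Among cells with 9000 to 11000 UMIs the median was 2989 genes at E12.5 (quartiles 2852 to 3139, 1905 cells) and 3312 at E13.5 (3215 to 3439, 131 cells). It was 2589 at E15.5 (2418 to 2755, 813 cells), 2358 at E18.5 (2199 to 2515, 833 cells) and 2521 at P5 (2376 to 2673, 1223 cells). Relative to E12.5 the medians were 1.11 times at E13.5, 0.866 at E15.5, 0.789 at E18.5 and 0.843 at P5. The quartile ranges of the 2 earliest ages lay above those of the 3 later ones. The order of E18.5 and P5 turned in cells with 18000 to 22000 UMIs, where the medians were 3633 and 3592 genes. The 131 E13.5 cells lay far above that library's median of 3004 UMIs. With 4500 to 5500 UMIs, E13.5 stood at 1.05 times E12.5 (762 and 174 cells). Barcodes at E12.5 may come from another list, so a difference in library chemistry cannot be told apart from age here.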

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

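The EGFP alternatives were fixed before the data were examined; all the CreERT2 ones were chosen after. Of 116 alternative values for 31 results, 72 stayed within the counting interval or spread of the reported value, 37 moved beyond it and 7 changed direction. Of those 72, 21 could not have changed, because P5 had 0 counts, no barcode was repeated, no E13.5 cell lay under 0.333 of the median or no EGFP count exceeded 1. The direction of some of the 37 moves was also set in advance. A higher minimum count or thinning to fewer UMIs lowers a share of positive cells by construction, so such moves do not show an unstable result. The lower level at E18.5 than at E15.5 stayed within its interval under the alternatives that gave a value. The comparisons with E13.5, the shallowest library, did not hold on unscaled measures. As log2 ratios, E13.5 over E12.5 (1.08) turned to -0.86 for UMIs per cell, -1.04 for the share with at least 1 UMI and -0.93 for the mean of log2(count + 1). It moved to 0.51 for the share with at least 2 UMIs, 0.29 at 4000 UMIs per cell and 0.49 without the top 1% of cells. E15.5 over E13.5 (-1.50) turned to 0.56, 0.26 and 0.40 on those 3 measures and to 0.94 for the share with at least 2 UMIs, and was -0.89 at 4000 UMIs per cell. Values from thinned cells kept the direction of the levels in CPM, but at 4000 UMIs, where 72.4% of E13.5 cells were left out, the intervals of the E12.5 and E13.5 shares overlapped. A minimum of 2 UMIs gave shares of 0.314%, 0.447%, 0.857% and 0.0903% at E12.5, E13.5, E15.5 and E18.5, and a minimum of 3 gave 0.0449%, 0.0745%, 0.274% and 0%. Thinning gave 0.609%, 1.42%, 0.443% and 0.0773% at 1500 UMIs and 1.66%, 2.03%, 1.09% and 0.200% at 4000. At E12.5 the share was 5.85% without the shallowest cells (under 0.333 of the median total) and 4.22% without cells above 2 times the median, where 3.42% of positive cells had at least 2 UMIs. Leaving out the 1% of cells with the highest counts gave 3.19, 4.50, 1.42 and 0 CPM, and by construction 0% of positive cells with at least 2 UMIs at E12.5, E13.5 and E15.5; no ratio for E18.5 could then be had. The mean of per-cell levels at E13.5 was 10.4 CPM. Positive cells with at least 2 UMIs had more genes than matched cells in 96.0% of cases at E15.5 and 25% at E18.5 (4 cells). EGFP gave 0 under a minimum of 2 or 3 UMIs, since no cell had more than 1, and 0 without the top 1% and as a median, since 0.162% of cells had any. Both settings tried for the EGFP level within positive cells left no cell and gave no value. No paired analysis was possible because each age has 1 library, and leaving out replicates was not possible for the same reason. The P5 meniscus comparison and the gene lists were not run.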

Other observations

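The tests on E13.5 cells, the share of UMIs in the shallowest E12.5 cells, the share of positive cells deeper than the median negative cell, the ratio without cells of at least 3 UMIs and the count of shared barcodes were chosen only after the result was seen; the other tests below were fixed before their results were seen.

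CreERT2 at E12.5 was closer to a spread by depth alone than at E13.5 and E15.5. Its 1.31-fold excess of cells with at least 2 UMIs was slightly above the range of 95% of simulated even spreads. In addition, 5 cells with 3 UMIs stood where 1.32 were expected. The lowest of the simulations with 1.0% of cells carrying all UMIs gave 2.85. That setting could not have held at E12.5, since 5.37% of cells were positive. Restriction to a larger share of cells was not simulated, so it stays open. Free RNA added in equal amount to every droplet is argued against, because the deepest of 4 equal groups of cells had 5.17 times as many UMIs per cell as the shallowest (3.90 to 6.96), close to their 5.37-fold ratio of depth. Barcodes that are not whole cells stay open. The 974 cells under 0.333 of the median depth held 0.627% of the CreERT2 UMIs (0.171 to 1.60). They held 1.21% of all UMIs, so a spread by depth alone would give a small share whatever they are. Their 4 CreERT2 UMIs lay in 4 cells, so none of them had at least 2. Without these cells the excess of cells with at least 2 UMIs was 1.30-fold, which was nearly fixed in advance and is no test. Whether deeper barcodes are whole cells was not tested. Doublets stay open: the level was 4.06 CPM without cells above 2 times the median depth, but a doublet has the level of its members, so this decides nothing. The share of positive cells deeper than the median negative cell was 72.1% (68.3 to 75.6), and 91.4% with at least 2 UMIs (76.9 to 98.2), where depth alone gives 73.6% and 89.5%, so it decides nothing either. Another library chemistry at E12.5 cannot be told apart from age, since the library shared 6 barcodes with the others (2.20 to 13.1) where 372 were expected and its barcodes may come from another list; broad weak expression of the reporter, free RNA that scales with a cell's depth and misassigned reads were not tested.

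The CreERT2 level was 7.64 times lower at E18.5 than at E15.5. With every cell thinned to 4000 UMIs the share of positive cells was 5.37 times higher at E15.5 (2.66 to 12.3, on rounded cell counts). The level in CPM is already divided by depth, so this nearly restates it and is no separate test of lower depth. Mean depth was 15177 UMIs per cell at E15.5 and 12911 at E18.5, a far smaller difference than that in level. The gap was smaller in the shallowest of 4 equal groups, with 3.81 CPM at E15.5 (2.85 to 5.00) and 1.31 at E18.5 (0.678 to 2.29). In the deepest group the levels were 2.82 (2.28 to 3.45) and 0 (up to 0.181). Whether the gap depends on the depth of the cell was not tested. A few cells with high counts at E15.5 are argued against, because without cells with at least 3 UMIs in either library the ratio of levels was 5.67 (3.67 to 9.15). A fall of Lgr5 transcription with age, a change in the cell types that the dissection released, embryos with different copies of the allele and the month of sequencing were not tested.

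At E13.5 the number of CreERT2 UMIs per cell hardly grew with depth: the deepest group had 1.14 times as many per cell as the shallowest (0.833 to 1.55), against a 3.14-fold ratio of depth. Free RNA added in equal amount to every droplet would leave cells with exactly 1 UMI no different from their neighbours in depth, yet 76.5% of them had more genes than matched negative cells (70.0 to 82.1), against 49.9% of negative cells. Doublets would be deeper than other cells, and 46.3% of positive cells (40.0 to 52.8) were deeper than the median negative cell, where depth alone gives 67.3%. Among the 42 with at least 2 UMIs it was 64.3% (48.0 to 78.4), where depth alone gives 83.5%. The share over all positive cells largely restates that their number hardly grew with depth. It is therefore no separate test of doublets, which stay open. Free RNA that varies between droplets was not tested, and no biological explanation was tested.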
